A study of Mus musculus with 22 samples.

How the data were processed

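Transcripts were measured in microglia (CD11b and CD45 positive) and astrocytes (GLT1 positive, CD11b negative) sorted from dissociated cortex of APP/PS1 mice and WT littermates, 7 and 7 microglia samples and 4 and 4 astrocyte samples. Per the labels, myelin and O4-positive cells were removed and dead cells gated away, RNA was amplified and labelled with Cy3 or Cy5, and each array held the APP/PS1 and the WT sample of the same number. The table holds single-channel log2 values as deposited by the authors, 22 columns from 11 arrays on 3 slides. The authors' notes name limma, with no version; the steps of background correction and normalization are not given in the sources used here. The distributions of the columns were near identical, the largest gap between samples being 0.205 log2 at any quantile from 5 to 95 percent, so a shift of all genes between samples could not be seen. Blank values were shared by both channels on 11 of 11 arrays and numbered 2249 to 10975 on microglia arrays and 151 to 593 on astrocyte arrays. The blank probes had medians of 2.46 to 2.90 on the other arrays. The highest value was 17.89, and 34 genes came within 0.5 of it.

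Of 43020 probes, 33026 named 1 gene, 0 named several and 9994 were unnamed and not used here. They covered 22485 genes, 6138 of them with more than 1 probe, and each gene was represented by the probe with the highest mean over the 22 samples. The gene identifiers of 32438 probes matched the RefSeq table, and 0 symbols changed on matching.

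The analysis used Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 (limma 3.58.1, statmod 1.5.0). Genotype effects were fitted with limma in 1 model of all 22 samples, with array as a fixed block, dye as a covariate and genotype nested in cell type. Both cell types shared 1 estimate of the spread and of the dye effect per gene, because the astrocyte arrays alone leave few residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The difference between cell types was the interaction contrast, astrocyte effect minus microglia effect. Astrocytes and microglia were compared with group means, dye and array as a random block; all astrocyte arrays lay on slide 3, so slide and cell type cannot be told apart there. The correlation of effects was computed across genes, with no p. The array pairing came from the labels. As a check, same-array samples, centred within their groups, correlated across genes at a median r of 0.47 (0.37 to 0.63) in microglia and 0.23 (0.00 to 0.50) in astrocytes. Samples of different arrays and genotypes gave -0.20 (-0.53 to 0.51) and -0.12 (-0.47 to 0.42), so the ranges overlap. Centring within groups lowers the values of different arrays where same-array ones are high, so the negative medians are partly built in.

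Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 19 pathway lists and, separately, over 11 marker lists. Because the table has blanks, camera was run in its pre-ranked form on the moderated statistics; camera with an estimated correlation and fry were run on the 16310 genes measured on all arrays. The pathway lists were disease-associated microglia genes, homeostatic microglia genes, interferon response, immunoproteasome and MHC class I, MHC class II, cytokines and chemokines, phagocytic receptors and uptake, lysosome, cholesterol and lipid handling, complement, cell cycle, immediate early and dissociation stress, pan-reactive, A1 and A2 astrocyte genes, astrocyte transport, metabolism and coupling, synapse-related astrocyte genes, oxidative phosphorylation and glycolysis. The marker lists covered astrocytes, microglia, neurons, oligodendrocytes and their precursors, endothelial, mural, perivascular macrophage and monocyte, lymphocyte, ependymal and erythroid cells. Some lists share members, so their results are not separate findings. For example, Ctsb and Cd63 are in the disease-associated and lysosome lists, and Aldoc is in the astrocyte marker, transport and glycolysis lists. With an estimated correlation 0 lists passed in either cell type or for the difference of effects, against 11, 19 and 17 pathway lists with fry in microglia, in astrocytes and for the difference. Some listed genes are withheld for evaluation and were not analysed here.

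The models, lists, alternatives and rule for named genes were set before the data were examined. Per cell type the rule named, among genes past 0.05 with the same sign on every array, the 10 largest rises and 10 largest falls; up to 4 members of each pathway list with the smallest adjusted p; transgene-related genes; chosen reactive and microglial genes; and the 2 brightest markers of each marker list. For the interaction it named the 5 largest positive and 5 largest negative differences. Not every gene under the rule is printed.

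Alternatives were no array block, array as a random block, no dye term, quantile normalization, median centring, only brighter genes, averaged or separate probes, an intensity trend, robust variance, sample weights, each cell type or slide alone, a looser threshold of 0.1 and leaving out each replicate. Added after the data were seen were only genes measured on every array, sex read from Eif2s3y as a covariate, only arrays whose samples match in it, and, for astrocytes, only genes not higher in WT microglia. Splits of the samples (at most 100, seed 1) were refitted.

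The share of microglial RNA in each astrocyte sample was the median, over 11 microglia markers outside the disease-associated list with a WT gap above 4 log2, of its level over that in microglia of the same genotype. The change this share predicts was set against the observed one over all measured members of a list, a predicted fall being limited to 1 log2. On simulated data, changes of 0.5, 1 and 2 log2 were recovered at 37.3, 62.7 and 83.3% in microglia, with 6 false calls, and at 16.4, 50.7 and 77.3% in astrocytes, with 3 false calls. Only 66 or 67 of 22375 genes were changed at each size, far fewer than were called in the data. Noise was drawn independently per gene with 1 spread for both cell types, so the false calls do not test the sharing of that spread.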

Results

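Microglia and astrocytes were sorted from the cortex of aged APPswe/PS1dE9 mice (APP/PS1) and wild-type littermates (WT), and their transcripts were measured on dual-colour Agilent arrays. APP/PS1 mice carry mutant transgenes driven by prion protein gene sequence, and form amyloid plaques in the cortex. The mice were between 15 and 18 months old. There were 7 APP/PS1 and 7 WT microglia samples and 4 APP/PS1 and 4 WT astrocyte samples, described as biological replicates. Each of the 11 arrays held the APP/PS1 and the WT sample of the same number and cell type in its 2 channels, and the dyes were exchanged between arrays. Per-sample medians of the deposited log2 values lay between 6.24 and 6.26. Microglia arrays had values for 32045 to 40771 of 43020 probes and astrocyte arrays for 42427 to 42869. The blank probes were dim by their medians on other arrays. Some bright ones were blank too, such as that of Tagln on the array of astrocyte replicate 2. The comparisons ask how each cell type in aged APP/PS1 cortex differed from the same cell type in WT littermates, and whether the effects differed between the cell types. Changes below are log2 differences, APP/PS1 minus WT, with their standard errors, and the number of arrays limits their precision.

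Most markers of the sorted cell types differed strongly between them. The glutamate transporter gene Slc1a2 was higher in astrocytes by 8.93 ± 0.28 log2 units, the water channel gene Aqp4 by 7.48 ± 0.35 and Aldh1l1, a folate enzyme used as an astrocyte marker, by 6.33 ± 0.25. The fractalkine receptor gene Cx3cr1, within 0.5 of the highest value in the table in 4 of 7 WT microglia samples, which limits its value, differed by -7.82 ± 0.50 (astrocytes minus microglia), Tmem119 by -7.96 ± 0.35 and the complement gene C1qa by -7.71 ± 0.41. Itgam, the gene of the sorting antigen CD11b, singled out after its values were seen, did not pass (-0.50 ± 0.21, adjusted p = 0.0515). This was its brightest probe (mean 13.52), and its other probes (means 10.1 and 7.33) were not compared between the cell types. With the genotype in astrocytes the brightest probe changed by -0.59 and the others by 0.37 and 0.87, not past the threshold. Markers of other cells were split between the samples. The endothelial gene Cldn5 (7.29 ± 0.33) and the oligodendrocyte lineage gene Olig2 (3.93 ± 0.32) were higher in astrocyte samples, while the myelin gene Mbp was higher in microglia samples (-5.16 ± 0.15). In all, 12471 of 22395 genes differed, 8255 higher in astrocytes and 4216 higher in microglia (limma, Benjamini-Hochberg adjusted p under 0.05). All astrocyte arrays lay on 1 slide of their own, and with slide as a random block 7484 genes passed.

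Microglia from APP/PS1 mice had much higher levels of genes known from plaque-associated microglia. Gpnmb, which encodes a transmembrane glycoprotein of phagocytic cells, rose from 6.18 ± 0.60 to 12.3 ± 0.26 (mean log2 ± SD, n = 7 each), a change of 6.16 ± 0.24 (limma adjusted p = 6.87e-07). The cystatin gene Cst7 rose by 4.99 ± 0.27, the lipoprotein lipase gene Lpl by 3.96 ± 0.31, the integrin gene Itgax by 2.62 ± 0.15 and the pattern recognition receptor gene Clec7a by 2.60 ± 0.25, each on 7 of 7 arrays. Genes typical of resting microglia moved the other way. Tmem119 fell by 1.42 ± 0.22 on the log2 scale, Cx3cr1, limited as above, by 1.25 ± 0.33 and the purine receptor gene P2ry12 by 0.89 ± 0.19, again on 7 of 7 arrays. Among genes with the same sign on all 7 arrays, other large rises were seen for Mamdc2 (6.10 ± 0.29), the prolyl hydroxylase gene Egln3 (5.38 ± 0.32), Etl4 (4.47 ± 0.25), C77080 (4.15 ± 0.21), Gm1673 (4.07 ± 0.09), Lgi2 (4.05 ± 0.27) and the heparanase gene Hpse (3.94 ± 0.23). The largest falls among these genes were those of the prostaglandin receptor gene Ptger3 (-2.19 ± 0.16), Rnase2a (-1.93 ± 0.58, but -1.24 without replicate 3), Dnah2 (-1.84 ± 0.35), the transcription factor gene Klf2 (-1.69 ± 0.18) and Rasd2 (-1.61 ± 0.20). They were followed by the clock gene Ciart (-1.60 ± 0.22), Tigd4 (-1.57 ± 0.15), the B cell scaffold gene Bank1 (-1.55 ± 0.19), the transcription factor gene Irf4 (-1.54 ± 0.21) and Ndrg4 (-1.53 ± 0.22).

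Across all genes, 4406 of 22375 (19.7%) differed in microglia, 1852 higher and 2554 lower, and 508 of the higher and 231 of the lower ones by more than 2-fold. Without the array as a block 1184 genes passed (739 higher, 445 lower), and the calls of Rnase2a (adjusted p = 0.0688), Trem2 (0.0859), Sall1 (0.0654), Cx3cr1 (0.106) and Ier2 (0.0688) were lost. Within the slides that held microglia, 1425 genes passed on slide 1 and 585 on slide 2. With the preset correlation 11 gene lists passed in microglia, and 0 with an estimated one. All 11 kept the sign of their median within both slides (disease-associated 1.29 and 1.28, homeostatic -0.73 and -0.93, interferon 0.82 and 1.01, cholesterol 1.19 and 1.22, glycolysis 0.75 and 0.72, cytokines 0.18 and 0.66 for slides 1 and 2). As many lists passed with the preset correlation in 21 of 100 splits of the microglia samples, the real one included, and some of these splits follow the genotypes in part. The call of Cx3cr1 was also lost without replicate 1, 3, 5, 6 or 7 (adjusted p = 0.0664, 0.0501, 0.0589, 0.0528 and 0.0631), and that of Rnase2a without replicate 1, 2, 4, 6 or 7 (0.0653, 0.0904, 0.102, 0.0717 and 0.0552).

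**Figure D1:**
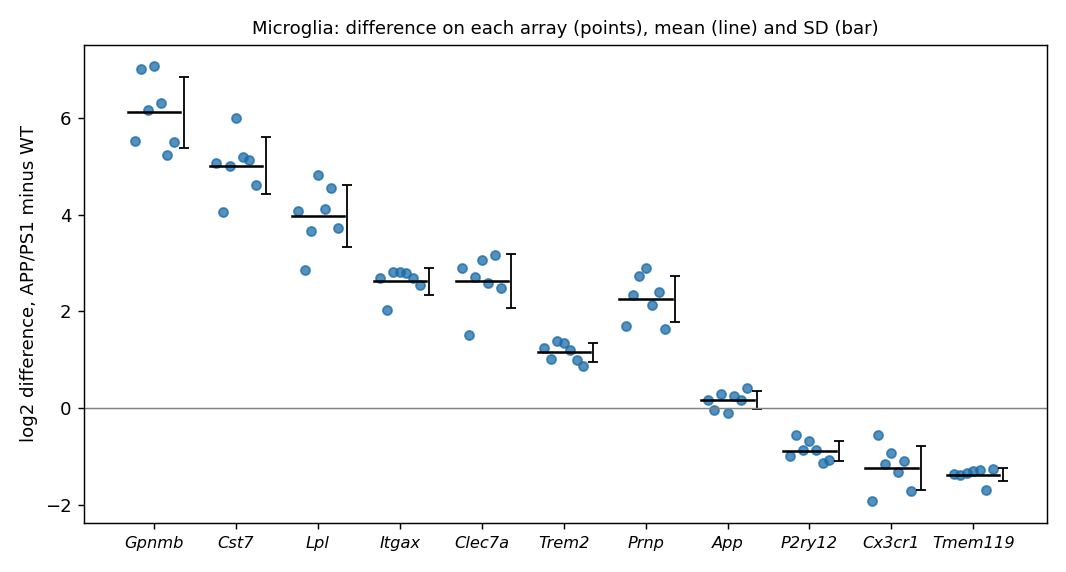
Log2 difference between the APP/PS1 and the WT microglia sample on each of 7 arrays (points), with the mean (line) and the SD over arrays (bar), for named genes. Gpnmb, Cst7, Lpl, Itgax, Clec7a, Trem2 and Prnp lie above 0 on every array and P2ry12, Cx3cr1 and Tmem119 below 0 on every array, while App was above 0 on 5 of 7.

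Of the 30 measured disease-associated microglia genes, 28 rose and 0 fell (29 and 0 adjusted over the list alone, median 1.26). Among them were the fatty acid binding protein gene Fabp5 (3.74 ± 0.18), the cholesterol hydroxylase gene Ch25h (3.63 ± 0.16) and the lipid-sensing receptor gene Trem2 (1.12 ± 0.22). The list passed camera with its preset correlation (adjusted p = 4.44e-28) and not with an estimated correlation (adjusted p = 0.0591). Of 22 homeostatic microglia genes, 18 fell and 0 rose (20 and 0 adjusted over the list alone, median -0.76, camera adjusted p = 1.37e-10, adjusted p = 0.264 with an estimated correlation). Examples were Txnip (-1.19 ± 0.10), the transcription factor gene Sall1 (-0.76 ± 0.09) and the matricellular protein gene Sparc (-1.11 ± 0.13, 6 arrays, 5 of 6 WT samples within 0.5 of the highest value in the table). Of 25 interferon response genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.83, camera adjusted p = 1.01e-13, adjusted p = 0.357 with an estimated correlation). Ifi27l2a (1.64 ± 0.19) and Usp18 (1.4 ± 0.17) were among them.

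Genes of lipid handling and glycolysis also rose in APP/PS1 microglia. Of 23 genes of cholesterol and lipid handling, 16 rose and 3 fell (16 and 4 adjusted over the list alone, median 1.18, camera adjusted p = 1.75e-10, adjusted p = 0.144 with an estimated correlation). Among them were the fatty acid binding protein gene Fabp3 (3.31 ± 0.13) and the lipid droplet gene Plin2 (1.82 ± 0.10). The list shares genes such as Lpl, Ch25h and Fabp5 with the disease-associated list. Of 19 glycolysis genes, 11 rose and 3 fell (13 and 4 adjusted over the list alone, median 0.75, camera adjusted p = 7.58e-08, adjusted p = 0.144 with an estimated correlation). Those that rose included the glucose transporter gene Slc2a1 (2.30 ± 0.17), Pgk1 (1.47 ± 0.11) and Tpi1 (1.37 ± 0.07). Of 26 lysosome genes, 12 rose and 2 fell (13 and 3 adjusted over the list alone, median 0.22, camera adjusted p = 9.27e-05, adjusted p = 0.438 with an estimated correlation). The cathepsin gene Ctsb (1.21 ± 0.14) and Cd63 (0.96 ± 0.10) rose and the legumain gene Lgmn fell by 0.89 ± 0.11. Of 27 oxidative phosphorylation genes, 4 rose and 1 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.0621). The list passed with quantile normalization (adjusted p = 0.031) and without replicate 1 (0.0446), 3 (0.0397) or 4 (0.0419). It also passed on the arrays whose samples matched in the Y-linked gene Eif2s3y (0.0487), an alternative chosen after seeing the data. Ndufa1 stood at 0.89 ± 0.06.

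Of 22 cytokine and chemokine genes, 8 rose and 0 fell (8 and 1 adjusted over the list alone, median 0.42, camera adjusted p = 1.52e-04, adjusted p = 0.438 with an estimated correlation). The interleukin genes Il12b (3.73 ± 0.32) and Il1b (2.49 ± 0.29), the chemokine gene Cxcl1 (3.12 ± 0.19) and the growth factor gene Csf1 (1.81 ± 0.13) were among them. Of 13 genes of the immunoproteasome and MHC class I, 2 rose (1 adjusted over the list alone, median 0.31, camera adjusted p = 0.0161, adjusted p = 0.607 with an estimated correlation, 0.141 with the list test fry), 1 of them the regulator Nlrc5 (1.16 ± 0.21, though its dimmer probe gave 0.19, adjusted p = 0.514). Of 11 MHC class II genes, 3 rose (4 adjusted over the list alone, median 0.25, camera adjusted p = 0.0303, adjusted p = 0.438 with an estimated correlation). Cd74 rose by 1.39 ± 0.26, and this list's call was lost without replicate 5 (adjusted p = 0.0596) or 6 (0.0863). The phagocytic receptor and uptake list was mixed, with 7 of 35 genes higher and 13 lower on both adjustments (camera adjusted p = 0.166, downward at 0.00612 with fry). The receptor kinase gene Axl rose by 2.71 ± 0.16 and the endocytosis gene Bin1 fell by 0.82 ± 0.09. Complement genes (3 higher and 2 lower of 16 on both adjustments, median -0.10 with an upward camera test at adjusted p = 0.731) included Cfb at 1.14 ± 0.21 on 6 arrays. Cell cycle genes (1 higher and 1 lower of 22 on both adjustments, camera adjusted p = 0.184) passed only without replicate 3 (adjusted p = 1.49e-04). Immediate early and dissociation stress genes (6 higher and 7 lower of 24, 6 and 9 adjusted over the list alone, camera adjusted p = 0.221) included Ier2 at 0.71 ± 0.10 and Myc at -1.05 ± 0.15.

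Most astrocyte markers were lower in the APP/PS1 microglia samples. Of 16 astrocyte markers, 10 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.85, camera adjusted p = 0.00171, adjusted p = 0.794 with an estimated correlation, 0.0611 with only genes above the median gene). Gfap, the intermediate filament gene of reactive astrocytes, was the 1 that rose (1.36 ± 0.13, to a level of 6.92 ± 0.41). Of 22 genes of astrocyte transport, metabolism and coupling, 9 fell and 1 rose (10 and 2 adjusted over the list alone, median -0.35, camera adjusted p = 0.0178, adjusted p = 0.679 with an estimated correlation, 0.0798 without replicate 2, 0.0743 with only genes above the median gene). Slc1a2 stood at -1.03 ± 0.13. Of 23 synapse-related astrocyte genes, 6 fell and 0 rose on both adjustments (camera adjusted p = 0.168). Among reactive astrocyte lists, A1 genes (2 of 10 higher on both adjustments, camera adjusted p = 0.0322, adjusted p = 0.438 with an estimated correlation, 0.0537 without replicate 2, 0.0514 with only genes above the median gene) passed. Pan-reactive genes (3 higher and 1 lower of 13, 5 and 1 adjusted over the list alone, camera adjusted p = 0.0651, 0.046 on genes measured on every array, 0.0253 without the array block, 0.0141 without replicate 3) and A2 genes (4 higher and 3 lower of 12, 5 and 3 adjusted over the list alone, camera adjusted p = 0.128) did not, although the prostaglandin synthase gene Ptgs2 rose by 3.27 ± 0.25. Of 16 neuron markers, 9 fell (11 lower and 1 higher adjusted over the list alone, median -0.48, camera adjusted p = 1.76e-04, adjusted p = 0.794 with an estimated correlation). With only genes above the median gene their median was -0.35 and the call was lost (adjusted p = 0.147). Of 13 markers of perivascular macrophages and monocytes, 6 fell on both adjustments (median -0.95, camera adjusted p = 0.00622, adjusted p = 0.794 with an estimated correlation, 0.101 without replicate 3, 0.0761 with only genes above the median gene). With fry the calls of the astrocyte markers (adjusted p = 0.0586), the transport genes (0.137), the A1 genes (0.0642) and the perivascular macrophage markers (0.0556) were lost. Pan-reactive (0.014) and A2 genes (0.0101) passed with it. The remaining marker lists did not pass: microglia (median -0.32), oligodendrocyte (0.18), oligodendrocyte precursor (0.03), endothelial (0.11), mural (0.11), lymphocyte (0.11), ependymal (-0.19) and erythroid (0.37). Leaving out 1 replicate gave calls to some of them, to lymphocyte markers without replicate 3 (median 0.49, adjusted p = 0.0245) and to endothelial (0.32, 0.0475) and oligodendrocyte markers (0.25, 0.0177) without replicate 2. Oligodendrocyte markers also passed with all probes of a gene averaged (0.0393).

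Astrocyte samples from APP/PS1 mice had higher levels of reactive astrocyte genes and of immune genes, and lower levels of genes of astrocyte transport and metabolism. Gfap rose from 7.61 ± 0.19 to 9.52 ± 0.57 (mean log2 ± SD, n = 4 each), a change of 1.90 ± 0.18 (limma adjusted p = 1.45e-04), and the intermediate filament gene Vim rose by 2.19 ± 0.43. Among genes with the same sign on all 4 arrays, the largest rises were in genes of microglia, led by Cst7 (5.04 ± 0.35), Clec7a (3.94 ± 0.33), Il1b (3.93 ± 0.38), the chemokine gene Ccl4 (3.84 ± 0.44) and the signalling adaptor gene Tyrobp (3.41 ± 0.25). Bcl2a1c (3.39 ± 0.32), Trem2 (3.32 ± 0.28), Ccl6 (3.30 ± 0.24), Lilrb4a (3.21 ± 0.28, though its dimmer probe gave 0.00, adjusted p = 0.997) and the cathepsin gene Ctss (3.02 ± 0.41) followed. The largest falls among them were in the Notch target gene Hes5 (-2.33 ± 0.30), Ppp1r3g (-2.23 ± 0.21), Amer2 (-2.14 ± 0.12), the glycerol phosphate dehydrogenase gene Gpd1 (-2.12 ± 0.19) and Fam181b (-2.10 ± 0.26). Igfbp2 (-2.08 ± 0.22), Rpe65 (-2.04 ± 0.25), the cholesterol synthesis gene Sqle (-2.03 ± 0.27), Dbx2 (-2.01 ± 0.28) and the transcription factor gene Etv5 (-1.96 ± 0.24) completed them, and all of these genes moved the same way on 4 of 4 arrays.

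Markers of other cell types moved with the genotype in the astrocyte samples. Of 15 microglia markers, 13 rose and 1 fell on both adjustments (median 2.04, camera adjusted p = 8e-07, adjusted p = 0.423 with an estimated correlation). Csf1r rose by 1.60 ± 0.36, though 1 of its other probes gave -0.09 (adjusted p = 0.722). By array the median microglia marker difference was 3.38, 1.97, 1.79 and 0.72 for replicates 1 to 4. Of 11 endothelial markers, 10 rose and 0 fell on both adjustments (median 1.17, camera adjusted p = 3.4e-05, adjusted p = 0.423 with an estimated correlation), and of 9 mural markers 6 rose (8 adjusted over the list alone, median 1.83, camera adjusted p = 3.4e-05, adjusted p = 0.423 with an estimated correlation). The smooth muscle genes Acta2 (1.83 ± 0.28) and Tagln (2.00 ± 0.32, 3 arrays) and the endothelial receptor gene Flt1 (0.90 ± 0.27) were examples. Acta2 in 3 of 4 and Tagln in 2 of 3 APP/PS1 samples came within 0.5 of the highest value in the table, 17.89, and their rises are limited by it. Of 7 ependymal markers, 4 rose on both adjustments (median 0.64, camera adjusted p = 0.0257, adjusted p = 0.423 with an estimated correlation, 0.0889 without replicate 3, 0.36 with only genes above the median gene). Of 16 astrocyte markers, 15 fell and only Gfap rose, on both adjustments (median -1.37, camera adjusted p = 1.56e-05, adjusted p = 0.551 with an estimated correlation). Aldh1l1 fell by 1.83 ± 0.21 on the log2 scale, the glutamate transporter gene Slc1a3 by 1.62 ± 0.23, Aldoc by 1.36 ± 0.28 and Clu, within 0.5 of the highest value in the table in 1 of 4 WT samples, which limits its value, by 0.93 ± 0.22. Neuron (median 0.13), oligodendrocyte (0.03), oligodendrocyte precursor (-0.34), perivascular macrophage (0.28), lymphocyte (0.74) and erythroid (0.40) markers did not pass as lists. The lymphocyte markers passed without the array block (adjusted p = 0.0204) and without replicate 3 (median 0.34, 0.0487), and the oligodendrocyte precursor markers with fry (0.0165).

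**Figure D2:**
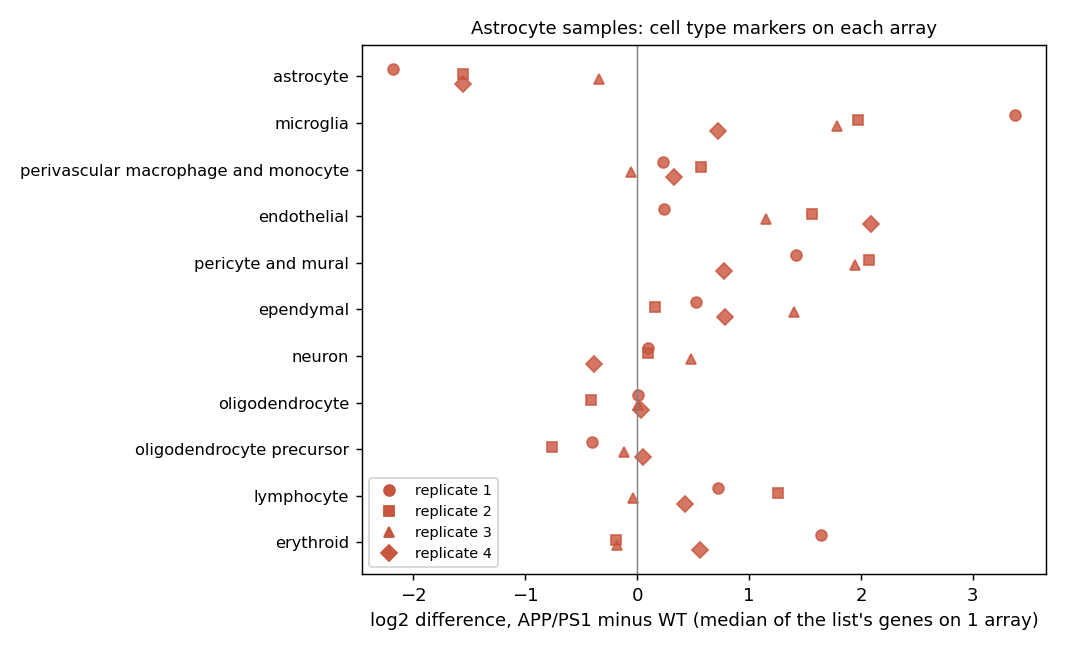
Median log2 difference between the APP/PS1 and the WT astrocyte sample of each array (symbols, 1 per replicate) for the marker lists of 11 cell types. Astrocyte markers lie below 0 on 4 of 4 arrays (-2.18 to -0.34) and microglia markers above 0 on 4 of 4 (0.72 to 3.38).

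In total 7515 of 22460 genes (33.5%) differed in astrocytes, 3465 higher and 4050 lower, and 1291 of the higher and 717 of the lower ones by more than 2-fold. Of the genes that rose, 54.2% were higher in WT microglia than in WT astrocytes, against 19.4% of those that fell and 37.0% of all genes. Both comparisons use the same WT astrocyte samples, so a gene low there by chance tends to count in both. The shares that no change would give were not computed. This limit holds as well for the list members counted this way below and for the restriction to genes not higher in WT microglia. Without the array as a block 2447 genes passed (1387 higher, 1060 lower), and the calls of Prnp (adjusted p = 0.121), Flt1 (0.0886) and Lamp2 (0.0611) were lost. Of the 19 lists 18 passed with the preset correlation and 0 with an estimated one. With the preset correlation 18 passed in 3 of 35 splits of the astrocyte samples, the real one included, and the others follow the genotypes in part. A fit of the astrocyte samples alone, with no spread shared with microglia, passed 2854 genes. The 2 arrays whose samples matched in the Y-linked gene Eif2s3y passed 4548. Among genes not higher in WT microglia than in WT astrocytes, 1581 were higher and 3242 lower. With sex read from Eif2s3y as a covariate 17 lists passed, and the calls of the homeostatic microglia genes (adjusted p = 0.0559), the ependymal markers (0.0641), Prnp (0.128), Flt1 (0.05) and Csf1r (0.0682) were lost. On the matching arrays the same calls were lost (0.12, 0.0986, 0.134, 0.0668 and 0.0694). The restriction to genes not higher in WT microglia, the sex covariate and the matching arrays were chosen after seeing the data.

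The 3 lists of reactive astrocyte genes passed upward with the preset correlation. Of 13 pan-reactive genes, 9 rose and 0 fell on both adjustments (median 1.27, camera adjusted p = 6.26e-06, adjusted p = 0.189 with an estimated correlation). Examples were the cytokine receptor gene Osmr (1.37 ± 0.15) and the lipid receptor gene S1pr3 (2.10 ± 0.24). Of 10 A1 genes, 8 rose on both adjustments (median 1.28, camera adjusted p = 1.64e-04, adjusted p = 0.189 with an estimated correlation). These included the complement inhibitor gene Serping1 (2.12 ± 0.30), H2-T23 (1.54 ± 0.23) and the immunoproteasome gene Psmb8 (1.30 ± 0.22). Of 12 A2 genes, 5 rose on both adjustments (median 0.78, camera adjusted p = 0.00114, adjusted p = 0.189 with an estimated correlation). They included Emp1 (1.65 ± 0.16) and Cd14 (2.45 ± 0.30), a receptor gene of myeloid cells. Of the genes that rose, 1 of 9 pan-reactive, 5 of 8 A1 and 3 of 5 A2 genes were higher in WT microglia than in WT astrocytes. The endothelial and mural markers given above rose in the same samples, by medians of 1.17 and 1.83.

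Of 25 interferon response genes, 24 rose and 0 fell on both adjustments (median 1.24, camera adjusted p = 9.51e-13, adjusted p = 0.189 with an estimated correlation). Of the 24, 10 were higher in WT microglia. Ifi27l2a rose by 2.33 ± 0.25 and the antiviral tether gene Bst2 by 1.62 ± 0.15. Of 13 immunoproteasome and MHC class I genes 12 rose (13 adjusted over the list alone, median 0.86, camera adjusted p = 6.95e-07, adjusted p = 0.231 with an estimated correlation), 11 of them higher in WT microglia. MHC class II genes (6 of 11 higher on both adjustments, all 6 higher in WT microglia, median 1.21, camera adjusted p = 0.00153, adjusted p = 0.189 with an estimated correlation) included Cd74 at 1.5 ± 0.34. Disease-associated microglia genes (17 higher and 3 lower of 30 on both adjustments, median 0.81, camera adjusted p = 1.33e-05, adjusted p = 0.189 with an estimated correlation) rose beside the microglia markers given above, and all 17 were higher in WT microglia. The same held for all 15 cytokine and chemokine genes that rose (15 higher and 1 lower of 22 on both adjustments, median 1.34, camera adjusted p = 6.26e-06, adjusted p = 0.189 with an estimated correlation). Il18 fell by 1.83 ± 0.18. It also held for all 12 homeostatic microglia genes that rose (12 higher and 6 lower of 22 on both adjustments, median 1.08, camera adjusted p = 0.013, adjusted p = 0.384 with an estimated correlation, 0.0502 without replicate 3). Entpd1 stood at 1.42 ± 0.12 and Sall1 at -1.44 ± 0.12. Phagocytic genes were mixed, though the list passed upward (16 higher and 4 lower of 35, 17 and 7 adjusted over the list alone, median 0.27, camera adjusted p = 0.00114, adjusted p = 0.189 with an estimated correlation). Of the 16, 14 were higher in WT microglia. Of 16 complement genes, 11 rose and 1 fell (12 and 3 adjusted over the list alone, median 1.62, camera adjusted p = 7.2e-05, adjusted p = 0.189 with an estimated correlation), 6 of the 11 higher in WT microglia. C1qa, itself a microglia marker, rose by 2.32 ± 0.31 and C5ar1 by 2.00 ± 0.20 on 3 arrays.

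Of 24 immediate early and dissociation stress genes, 19 rose and 0 fell (21 and 0 adjusted over the list alone, median 1.16, camera adjusted p = 1.21e-11, adjusted p = 0.189 with an estimated correlation). Examples were Fos (2.21 ± 0.23), Fosb (1.47 ± 0.14) and the signalling inhibitor gene Socs3 (1.32 ± 0.13), and 17 of the 19 were higher in WT microglia. Of 22 cell cycle genes, 7 rose on both adjustments (median 0.38, camera adjusted p = 0.00114, adjusted p = 0.335 with an estimated correlation). Examples were the replication gene Mcm6 (1.39 ± 0.19) and the cyclin gene Ccnd1 (0.93 ± 0.10), and all 7 were higher in WT microglia.

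Genes of astrocyte function fell. Of 22 genes of transport, metabolism and coupling, 21 fell and 0 rose on both adjustments (median -1.25, camera adjusted p = 5.97e-09, adjusted p = 0.231 with an estimated correlation). Examples were the potassium channel gene Kcnj10 (-1.69 ± 0.19) and the glutamate dehydrogenase gene Glud1 (-1.18 ± 0.13). Of 23 synapse-related astrocyte genes, 11 fell and 3 rose (12 and 3 adjusted over the list alone, median -0.66, camera adjusted p = 0.0165, adjusted p = 0.308 with an estimated correlation). The adhesion gene Nrcam stood at -1.67 ± 0.22 and the proteoglycan gene Ncan at -1.27 ± 0.19. Of 23 genes of cholesterol and lipid handling, 12 fell and 4 rose (15 and 4 adjusted over the list alone, median -0.67, camera adjusted p = 0.00931, adjusted p = 0.369 with an estimated correlation). The synthesis genes Hmgcs1 and Idi1 stood at -1.94 ± 0.16 and -1.65 ± 0.17. Of 19 glycolysis genes, 10 fell and 1 rose on both adjustments (median -0.38, camera adjusted p = 0.0129, adjusted p = 0.334 with an estimated correlation). Pfkm stood at -1.36 ± 0.17 and Tpi1 at -0.75 ± 0.09. Of 27 oxidative phosphorylation genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone, median -0.19, camera adjusted p = 0.00211, adjusted p = 0.41 with an estimated correlation). Sdhb stood at -0.72 ± 0.10 and Ndufa1 at 0.66 ± 0.08. The lysosome list did not pass (4 higher and 11 lower of 26, 4 and 13 adjusted over the list alone, camera adjusted p = 0.0976, 0.043 without replicate 3, 0.0133 with fry, 0.0419 on the matching arrays), and Lamp2 fell by 0.83 ± 0.11. The other probes of Sdhb (-0.28, adjusted p = 0.0826), Tpi1 (-0.30, 0.0927) and Lamp2 (-0.30, 0.0815) did not pass. These falls stood beside the fall of the astrocyte markers, with which the transport list shares genes such as Slc1a2, Slc1a3, Aqp4, Aldh1l1 and Aldoc.

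**Figure D3:**
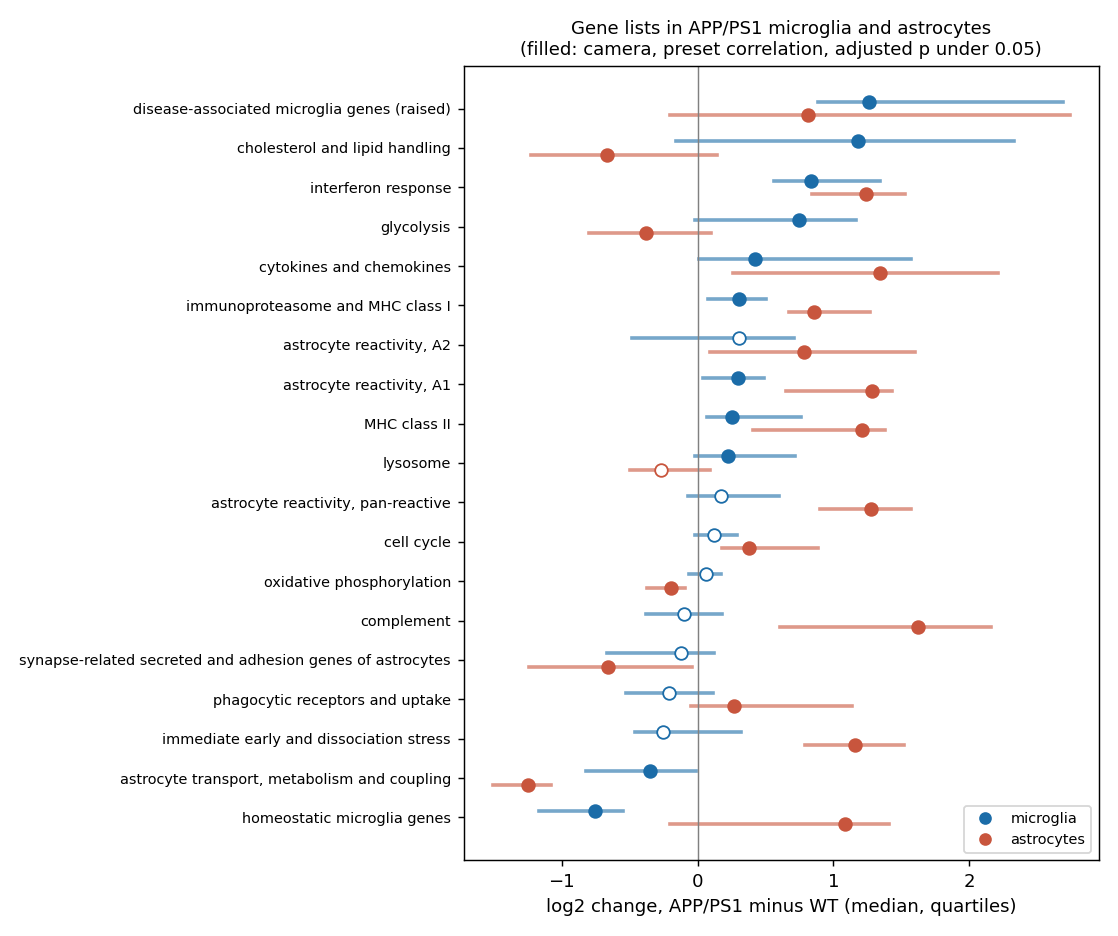
Median log2 change (APP/PS1 minus WT, points) and quartiles (lines) of 19 gene lists in microglia and in astrocytes, with filled points for lists that passed camera with the preset correlation. Cholesterol and lipid handling lies at 1.18 in microglia and -0.67 in astrocytes, and glycolysis at 0.75 and -0.38. Astrocyte values were not corrected for RNA of other cell types in the samples.

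The effects of the genotype differed between the cell types for 5953 of 22380 genes, 3004 with a higher and 2949 with a lower effect in astrocytes (limma interaction contrast, adjusted p under 0.05). Genes of lipid handling and glycolysis had lower effects in the astrocyte samples. Astrocyte markers also fell and endothelial and mural markers rose in those samples. Falls of lipid handling and glycolysis genes there need therefore not be changes within astrocytes. Cholesterol and lipid handling had 17 of 23 genes with a lower effect in astrocytes and 1 with a higher one on both adjustments (median difference -1.79, camera adjusted p = 2.85e-10, adjusted p = 0.148 with an estimated correlation). Sqle rose by 1.90 ± 0.20 in microglia against its fall in astrocytes (difference -3.94 ± 0.33), Hmgcs1 by 0.85 ± 0.12 (-2.79 ± 0.20) and Idi1 by 1.30 ± 0.13 (-2.94 ± 0.21). Glycolysis showed the same pattern, with 13 of 19 genes lower and 0 higher on both adjustments (median -1.01, camera adjusted p = 7.79e-09, adjusted p = 0.148 with an estimated correlation). Tpi1 stood at -2.12 ± 0.12. Immediate early genes had a higher effect in astrocytes, 19 of 24 (22 adjusted over the list alone, median 1.19, camera adjusted p = 1.92e-11, adjusted p = 0.172 with an estimated correlation). So did homeostatic microglia genes, with 15 higher and 2 lower of 22 (16 and 2 adjusted over the list alone, median 1.60, camera adjusted p = 2.38e-06, adjusted p = 0.27 with an estimated correlation). The microglia markers had a median difference of 2.45. These differences were not corrected for the microglial RNA in the astrocyte samples, weighed below. Higher effects of microglial genes there need therefore not be responses of astrocytes.

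The largest single differences towards microglia were Gpnmb (-5.52 ± 0.39), Fabp5 (-5.45 ± 0.29), its near-identical copy Fabp5l2 (-5.39 ± 0.32), whose probes may read the same transcripts, Sox7 (-5.14 ± 0.47, 5 microglia arrays) and Egln3 (-5.14 ± 0.52). Those towards astrocytes were Sbp (4.29 ± 0.66), Clec2m (4.18 ± 0.85), Syt4 (4.16 ± 0.51), Olfr1322 (3.96 ± 0.33) and 1700049E15Rik (3.93 ± 0.61, 4 microglia arrays). Sbp, Clec2m, Syt4 and Olfr1322 were each measured on only 1 microglia array, so their microglia effect has no spread of its own. The probe of 1700049E15Rik had a mean level of 2.26, below the medians of 2.46 to 2.90 of blank probes on other arrays. Its difference is therefore that of a dim probe. The other probe of this gene, at 2.25, gave 0.97 in microglia and -0.24 in astrocytes. The call of Sbp was lost without astrocyte replicate 4 (adjusted p = 0.0659), and that of Clec2m without astrocyte replicate 1, 2, 3 or 4 (0.0934, 0.0578, 0.0587 and 0.0618). Without the array as a block 1491 genes passed, and the calls of Syt4 (adjusted p = 0.206) and Olfr1322 (0.0542) were lost.

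Across 22375 genes tested in both cell types, the effects correlated weakly (Pearson r = 0.099, Spearman rho = 0.075, genes are not independent replicates). With only genes above the median gene r was 0.175. The lists of calls overlapped more than independent lists would: 597 genes rose in both against 286 for independent lists, and 839 fell in both against 462. Opposite calls exceeded independence less, with 393 genes higher in microglia and lower in astrocytes against 335, and 495 lower in microglia and higher in astrocytes against 395. Both tests share 1 estimate of the spread per gene, so unrelated effects could also give more shared calls than independent lists. Microglial RNA in the astrocyte samples, weighed below, may add to the shared rises.

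Of the genes related to the transgenes, Prnp rose in microglia by 2.30 ± 0.15 (adjusted p = 7.74e-06), and its 10 probes gave 2.24 to 2.30. Probe sequences were not used, so these probes may repeat 1 sequence and their agreement may not be independent evidence. In astrocytes Prnp, which was far more abundant there (16.2 ± 0.05 in WT), fell by 0.67 ± 0.19 (adjusted p = 0.0224, 0.103 without replicate 1 and 0.0991 without replicate 4). App was 0.14 ± 0.15 in microglia (adjusted p = 0.583) and rose by 1.22 ± 0.20 in astrocytes (adjusted p = 0.0014). Whether these mouse probes match the transgenes is not known. The labels give no sex, and the Y-linked gene Eif2s3y was at 9.63 or more in 9 samples and at 4.83 or less in the others. On 3 arrays, those of microglia replicate 1 and astrocyte replicates 1 and 3, the APP/PS1 sample was high and the WT sample low, and all 4 WT astrocyte samples were low. The dye term passed for 291 genes, 155 higher and 136 lower in Cy5.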

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

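The tests of the 3 patterns weighed here were chosen after the results were seen; the comparisons of sample splits were set beforehand.

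Microglial and immune gene lists were higher in APP/PS1 astrocyte samples, beside microglia markers. Levels of 11 microglia markers set the share of microglial RNA at 0.434, 0.143, 0.168 and 0.516% of the microglial level in WT samples 1 to 4 and at 5.05, 0.973, 1.01 and 1.08% in APP/PS1 samples 1 to 4, although the sort had gated CD11b-negative cells; Csf1r, an abundant marker, stood at 9.94 in WT astrocytes and 17.55 in WT microglia. RNA of microglia was excluded as the whole cause for the 25 interferon genes (median observed minus predicted change 1.09, quartiles 0.79 and 1.42) and the 13 pan-reactive genes (1.23, quartiles 0.79 and 1.43). For the 30 disease-associated genes (-0.27, quartiles -0.60 and 0.31) such RNA and a change within astrocytes cannot be told apart, since 14 came within 0.5 of the prediction, among them Cst7 (5.04 observed, 5.24 predicted) and Trem2 (3.32 and 3.57), 6 lay above it (Lpl 2.30 and 0.80, B2m 1.41 and 0.08, Ch25h 1.62 and 0.40, Lgals3 1.52 and 0.42, Cd9 0.99 and 0.18, Cd52 2.88 and 2.29) and 10 below it, down to Fabp5 (-1.71 and 0.01) and Cd68 (1.4 and 2.49), members singled out after their values were seen. A change within astrocytes, or in another cell type in the samples, stays open for all 3 lists.

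Astrocyte markers were lower in APP/PS1 astrocyte samples while endothelial, mural and microglia markers were higher. A lower share of astrocytes with all other cell types alike would raise endothelial and oligodendrocyte markers alike, but their medians differed by 1.13. This does not exclude it, since myelin and O4-positive cells were removed and oligodendrocyte markers may be too low to show a rise. Different sex of the paired mice was excluded as the whole cause. The median astrocyte marker change was -1.50 (quartiles -1.80 and -1.38) on the 2 arrays whose samples matched. RNA of microglia alone was excluded, since its share predicts by dilution a fall of at most -0.068 on any array, against a median of -1.37. More RNA of vascular cells with it would lower all markers by a common amount, but the ratio of their SD to their standard error decides nothing, since 3.49 for the list rests on Gfap alone, known to have risen, and 1.05 on the 15 markers chosen for having fallen. RNA of vascular cells and a change within astrocytes cannot be told apart, since no sample of vascular cells gives their share. The sort had gated GLT1-positive cells, yet the endothelial gene Cldn5 stood at 14.88 to 16.02 in WT astrocyte samples.

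Prnp was higher in APP/PS1 microglia. RNA of astrocytes, where Prnp is abundant, was excluded as the source, since astrocyte markers moved by a median of -0.85 in the same samples (quartiles -1.04 and -0.57). A transcript of the transgenes, which carry Prnp sequence, and a change of the endogenous gene cannot be told apart: App changed by 0.14 in microglia (95% interval -0.20 to 0.49), but whether its probe matches the transgene is not known. In astrocytes App rose by 1.22 and Prnp fell by 0.67 on the log2 scale.

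Other splits of the samples show whether chance can be excluded. It can for the gene counts in microglia (4406, highest other 2208), where 1 of 100 splits, the real one, gave as many. The same held for the difference of effects (5953 and 10, 1 of 100) and between cell types (12566 and 7075, 1 of 100, on array means). In astrocytes 1 of 35 splits gave as many genes (7515, highest other 4392), but the 8 splits that part every array are too few for a share under 0.05 (highest other 3). Chance cannot be excluded for the gene lists, with 11 lists in microglia against up to 15 (21 of 100 splits; 10 of the 64 that part every array, up to 16) and 18 in astrocytes against up to 18 (3 of 35; 1 of those 8, highest other 16). The microglia split with 2208 genes parted only arrays 2, 4 and 6 (arrays are named by replicate number) and the 2 astrocyte splits with 4392 genes and 18 lists only arrays 1 and 2, so these follow the genotypes in part. In microglia the other splits that part every array and gave as many lists turned 1, 2 or 5 of the 7 arrays. The astrocyte split with 16 lists turned 1 array. These also follow the genotypes in part, up to sign, so the list counts can neither exclude nor show chance. Splits that leave arrays unparted have fewer arrays to show an effect, so the 64 microglia splits that part every array compare more fairly. Among these 64 only the real one gave as many genes, and the highest other gene count was 33. Without the array block the real counts were 1184 and 2447.

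Single samples lay far from the others of their group in 17 of 227 groups, where chance gives about 1 in 20. By kind these were 6 of 64 list differences (chance 3.2), 5 of 44 marker levels (chance 2.2) and 6 of 119 gene differences (chance 6). The genes set apart were thus no more than chance gives. For list medians (APP/PS1 minus WT), these were cholesterol genes on astrocyte array 3 (-0.03, others -0.85), cell cycle genes on microglia array 3 (-1.18, others 0.06 to 0.56), transport genes on microglia array 3 (0.02, others -0.61 to -0.35), synapse-related genes on microglia array 7 (-0.48, others -0.18 to -0.04), sex-linked genes on microglia array 1 (2.77, others -0.68 to 0.40) and oligodendrocyte markers on astrocyte array 2 (-0.41, others 0.01 to 0.04). For mean marker levels they were microglia markers in APP/PS1 astrocyte sample 1 (10.52, others 8.36 to 8.66), oligodendrocyte precursor markers in WT astrocyte sample 3 (7.64, others 7.82 to 7.85), endothelial (6.15, others 7.26 to 7.79) and mural markers (5.35, others 6.27 to 6.83) in WT microglia sample 4, and perivascular macrophage markers in WT microglia sample 3 (11.49, others 8.18 to 9.18). For genes they were Rnase2a on microglia array 3 (-6.54, others -1.63 to -0.71), Itgax (2.02, others 2.54 to 2.82) and Clec7a (1.5, others 2.49 to 3.17) on microglia array 2, Tmem119 (-1.69, others -1.38 to -1.27) and Bin1 (-1.21, others -0.83 to -0.56) on microglia array 6, and Sqle on astrocyte array 3 (-1.03, others -2.40 to -2.31).

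The effect of the genotype differed between the cell types, by camera on the interaction with its preset correlation, for 15 pathway and 7 marker lists, and for 0 of either with an estimated correlation. Median differences (astrocyte minus microglia effect) were -0.60 for disease-associated, 1.60 for homeostatic, 0.34 for interferon, 0.59 for MHC class I, 0.48 for phagocytic, -0.51 for lysosome, -1.79 for cholesterol, 1.46 for complement, 0.31 for cell cycle, 1.19 for immediate early, 1.02 for pan-reactive, 0.82 for A1, -0.75 for transport, -0.24 for oxidative phosphorylation and -1.01 for glycolysis genes. The marker lists gave -0.54 for astrocytes, 2.45 for microglia, 0.69 for neurons, 1.20 for endothelial, 1.70 for mural, 1.24 for perivascular macrophage and 1.26 for ependymal cells. No list was corrected for RNA of other cell types in the astrocyte samples. MHC class II (0.35), cytokine (0.49), A2 (0.65) and synapse-related genes (-0.48) did not pass. On genes measured on every array the calls of disease-associated (adjusted p = 0.117), cell cycle (0.0618) and astrocyte marker genes (0.0694) were lost, and cytokine (0.0439), A2 (0.0434) and synapse-related genes (0.0456) passed.

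Of 116 named genes tested for the difference, 92 passed, against 5953 of all 22380 genes (26.6%). Many were named for their size or adjusted p in these data, some of them for this same difference. A higher share among them was therefore built in. Sbp, Clec2m, Syt4 and Olfr1322 were measured on 1 microglia array each, so their microglia effect has no spread of its own, and Acta2, Tagln, Csf1r, Cx3cr1 and Sparc came within 0.5 of the highest value in the table in some samples, which limits their values. The value of 1700049E15Rik rests on a probe as dim as blank ones. The values were not corrected for RNA of microglia or vascular cells in the astrocyte samples. Higher effects of microglial genes such as Cx3cr1, Csf1r and C1qa need therefore not be responses of astrocytes. The log2 effect was higher in astrocytes for Sbp 4.29, Clec2m 4.18, Syt4 4.16, Olfr1322 3.96, 1700049E15Rik 3.93, Ccl4 3.92, Cx3cr1 3.30, Ptger3 3.29, Dnah2 3.19, Csf1r 2.94, Ctss 2.88, Klf2 2.77, Tyrobp 2.57, Txnip 2.52, C1qa 2.51, Rasd2 2.51, Tmem119 2.45, Fos 2.41, Irf4 2.39, Trem2 2.20, S1pr3 2.17, Serping1 2.14. It was also higher for Bank1 1.99, Ccl6 1.98, Socs3 1.87, Tagln 1.86, Bcl2a1c 1.84, Entpd1 1.79, Acta2 1.70, C5ar1 1.46, Sparc 1.42, Ccnd1 1.37, Tigd4 1.34, Clec7a 1.34, Mcm6 1.29, Bin1 1.27, Lilrb4a 1.18, Emp1 1.14, Fosb 1.11, App 1.08, H2-T23 1.07, Bst2 1.06, Osmr 1.02, Psmb8 1.00, Myc 0.85. The effect was lower in astrocytes for Gpnmb -5.52, Fabp5 -5.45, Fabp5l2 -5.39, Egln3 -5.14, Sox7 -5.14, Gm1673 -4.67, Mamdc2 -4.39, Sqle -3.94, Etl4 -3.27, C77080 -3.19, Prnp -2.97, Idi1 -2.94, Hmgcs1 -2.79, Lgi2 -2.71, Hpse -2.53, Axl -2.45, Pgk1 -2.30, Tpi1 -2.12, Ch25h -2.01, Aldh1l1 -2.0, Slc2a1 -1.98, Ctsb -1.84, Igfbp2 -1.83. It was also lower for Flt1 -1.82, Fabp3 -1.79, Cd63 -1.78, Plin2 -1.76, Amer2 -1.72, Csf1 -1.72, Rpe65 -1.68, Lpl -1.65, Il18 -1.56, Kcnj10 -1.51, Cxcl1 -1.46, Hes5 -1.44, Ppp1r3g -1.42, Etv5 -1.30, Ptgs2 -1.28, Ncan -1.15, Dbx2 -1.08, Gpd1 -1.07, Pfkm -1.05, Lamp2 -1.01, Slc1a3 -0.92, Glud1 -0.89, Sall1 -0.68, Sdhb -0.62.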

How the results depend on the processing

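The alternatives marked here as added were chosen after the data were seen.

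Without the array block 1184 genes passed in microglia (1182 of the 4406 kept, all 4406 with the same sign), 2447 in astrocytes (2439 of 7515 kept), 1491 for the difference of effects (1486 of 5953 kept) and 98 for dye. Slide 1 alone gave 1425 microglia genes and slide 2 alone 585, from fewer samples. The astrocyte samples alone gave 2854 and the microglia samples alone 4947, each without the spread shared between the cell types. Arrays whose samples match in Eif2s3y (added, fewer samples) gave 4548 in astrocytes and 3963 for the difference. With genes not higher in WT microglia (added, 14090 genes tested), 4823 passed in astrocytes. It removes every member called higher of the lists whose medians reversed, disease-associated -0.51 (adjusted p = 0.455), homeostatic -1.23 (0.0206), MHC class II -0.44 (0.742) and cytokines -1.29 (0.165), but also of cell cycle, whose median stayed at 0.02 (0.522). Only genes above the median gene gave 705 dye calls, and slide as a random block gave 7484 genes between cell types. With an estimated correlation 0 lists passed in microglia and 0 in astrocytes. The causes of these shifts were not tested, also where fewer genes or samples were used.

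Leaving out 1 replicate gave 3300 to 3923 genes in microglia, 5521 to 6839 in astrocytes and 4401 to 5942 for the difference, with 9 to 14 lists in microglia and 18 in astrocytes. The other alternatives run kept each of these counts within 1.5-fold. Of 2711 values of named genes, 2627 kept direction and call, 84 lost the call (38 of 131 results) and 0 reversed. Of 898 values of gene lists, 810 kept both, 62 lost the call, 22 gained it and 4 reversed. Up to 10975 probes of a microglia array were blank, dim ones by their median, which limits what can be seen there.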

Other observations

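WT microglia sample 3 had the highest perivascular macrophage and monocyte marker level of its group (11.49, others 8.18 to 9.18). The neutrophil genes S100a9, S100a8, Chil3 and Plac8, singled out after their values were seen, stood at 17.7, 16.5, 13.8 and 11.8 in it.

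The 3 probes of Gfap gave 1.36, 0.97 and 0.28 in microglia and 1.90, 1.35 and 0.62 in astrocytes, the third not past the threshold in either. Across the 7 microglia arrays the median difference of astrocyte markers lay between -0.99 and -0.27, and that of disease-associated genes between 1.02 and 1.75.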
